A study of Drosophila melanogaster with 6 samples.

How the data were processed

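The series measured m6A sites by miCLIP in S2R+ cells. Per the labels, poly(A) RNA was fragmented and immunoprecipitated with an anti-m6A antibody in 4 replicates and in 1 non-crosslinked control, and 1 library of fragmented mRNA served as input. Nothing in the labels says whether the replicates came from separate cultures.

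The submitters' processing notes name the genome build dm6, cutadapt 1.8, Bowtie 1.1.2, Novoalign, BWA and STAR 2.4.2a, without the role of each. Per the file headers and the column legend deposited with them, sites were called with the CTK toolkit from alignments by Novoalign, STAR and BWA, and a site was listed when 2, 3 or 4 of the IPs shared it. The authors listed crosslink-induced C-to-T mutation sites and truncation sites apart. For C-to-T sites the deposited values are k, the number of unique tags over the position, m, the number of those with the change, and their ratio as a percent, each a mean of the IPs that share the site, together with the lowest false discovery rate. For truncation sites the deposited values are the peak height PH, its null value and a p-value as CTK gives them, and the base at the truncation; how these were combined over IPs is not given in the sources used here, which limits comparisons of PH between sites found in different numbers of IPs. Each value is given for the 3 aligners, and the mean over the aligners that gave the site was used here; a site's number of IPs is the highest over aligners. The listed false discovery rate was 0 at every C-to-T site, so it could not rank sites. m and PH, averaged in this way, were taken as the authors' score, a definition chosen after the columns were seen.

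Since only combined values are listed, no spread between replicates can be given and leaving out a replicate was not possible. No site value of the non-crosslinked control or of the input was used here, so no site was compared here with a background library; whether the authors filtered the listed sites against these controls is not given in the sources used here. Depth is known only as k at listed C-to-T sites, and coverage elsewhere is unknown. Wilson 95% intervals cover counting error only.

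Sites were placed on genes of Ensembl release 115 (assembly BDGP6.54, dm6 coordinates) on the same strand, 1-based. Where isoforms differ a position counted as 5' UTR first, then coding sequence, then 3' UTR, and 152 C-to-T and 418 truncation sites in exons of more than 1 gene went to the gene the authors named or, failing that, to the first by symbol. Of the authors' gene names, 1323 of 1352 in the C-to-T list and 3939 of 4086 in the truncation list matched an annotated symbol or synonym. The authors' part label was the same as in the annotation for 94.4% and 95.4% of sites, but for 70.7% of C-to-T and 81.1% of truncation sites they labelled 3' UTR.

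Expected shares came from the length of each transcript part in the same gene, with 10000 random draws for a two-sided permutation p, the smallest possible being 0.0002, and 1000 resamples of genes for the interval of each ratio. For sites shared by the lists, control positions lay at least 10 nt from any C-to-T site in the same part of the same gene; they were not kept away from truncation sites, which would have fixed the outcome, and they were not matched on base. Score differences used 100000 resamples. Gene lists were compared by Fisher's exact test with Benjamini-Hochberg adjustment over 22 lists, and 6 listed names found no match. Motif results (DRACH, pentamers and flanking bases) and base-matched controls need the genome sequence, which was not used here; in their place the base at truncations and the pairing of both kinds of site were described, choices made after the files were seen. A pair means a C-to-T site with a truncation at A exactly 1 nt upstream.

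Genes were named by rules fixed before the data were examined: the 15 with the most exonic sites, the 10 with the most C-to-T sites that have a truncation within 3 nt, the 5 highest sites of each list, up to 4 members of each gene list with the most sites, and every member with a site of the m6A list, which holds Fmr1, and the cytoskeleton list. The DRACH condition in these rules was dropped.

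Alternatives covered score filters, merged sites, isoform choice, part order, support by 4 IPs, the left-out top 10 genes and overlap windows, and others chosen after seeing the data: sites found with all 3 aligners, the authors' part labels, truncations at A only and paired sites only. The functions were tested on simulated data, with sites placed independently within genes, so clustered sites and uneven coverage were not covered. Uniform sites in the 1300 C-to-T genes gave a 5' UTR call in 0 of 20 runs. Sites drawn with a planted 5' UTR excess of 2.01 times gave a mean ratio of 2.01 and a call in 20 of 20. Truncations planted 1 nt from 30% of C-to-T sites were recovered as an excess of 29.4 percentage points in sites with a truncation within 3 nt. The base and the upstream position were not simulated, so pairs as defined here were not tested. Of 1000 random gene lists, 46 passed an unadjusted threshold of 0.05. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.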

Results

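N6-methyladenosine (m6A) was mapped by miCLIP in S2R+ cells, a Drosophila line of haemocyte-like character grown in culture. In miCLIP an m6A antibody is crosslinked to fragmented mRNA, and reverse transcription past the crosslink leaves a C-to-T change or stops, so that methylated positions are read from mutations and from truncated cDNAs. The 6 samples were 4 replicate m6A immunoprecipitations (IPs), 1 non-crosslinked IP control and 1 fragmented mRNA input control. The site values used here are combined over the 4 IPs, so they carry no SD or n, and the controls are not analysed here. Tests below compare sites with positions, or genes with genes, and never samples with samples.

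The C-to-T list held 6225 sites and the truncation list 22917 sites. Of these, 5895 C-to-T sites (94.7%) and 19715 truncation sites (86.0%) lay in exons of nuclear protein-coding genes, in 1300 and 3802 genes, of which 1295 bore sites of both kinds. C-to-T sites were covered by a median of 274 unique tags, from 20 to 2990.5, of which a median of 8.17 carried the change. The conversion rate was low, with a median of 3.43% (quartiles 1.99% and 5.69%) and a highest value of 19.9%. Sites were seen in all 4 IPs for 34.6% of the C-to-T list and 27.4% of the truncation list.

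The first question was which mRNAs carried the most sites. The translation elongation factor genes eEF1alpha1 (146 sites, 110 of them C-to-T) and eEF2 (125 sites, 79 of them C-to-T) led the count. They were followed by nocte and LanA, a laminin subunit, with 96 sites each, and by sty, which encodes the receptor tyrosine kinase inhibitor Sprouty, with 74. The next were Xrp1 (70), pAbp (69), the ETS factor gene pnt (65), eEF1gamma (63), bun (58), RpL23A, aqz and SREBP (57 each), RpL8 (55) and Hsc70-4 (54). Counts per gene can rise with mRNA abundance and length, neither of which is given by site lists, and this was not tested.

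These genes fell into contrasting layouts. In eEF1alpha1 (chromosome 2R, 11891135 to 11895762, plus strand) 68 C-to-T sites lay in the coding sequence, 39 in the 3' UTR and 3 in the 5' UTR, with a median conversion of 0.981% at a median of 1152 tags. In pnt (chromosome 3R, 23290231 to 23346167, minus strand) all 39 C-to-T sites lay in the 5' UTR, as did 38 of the 45 in sty and all 22 in pum, the gene of the translational repressor Pumilio. The C-to-T sites of aop, an ETS repressor gene, also lay in the 5' UTR without exception (19 of 19), and 11 of them had a truncation at A directly upstream. eEF1alpha1, eEF2, pAbp, eEF1gamma, RpL8 and Hsc70-4 had 0 such pairs.

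The second question was which base was marked. A was the base at 51.9% of truncation sites (95% Wilson interval 51.3% to 52.6%), T at 32.5% (31.8% to 33.1%), G at 8.14% and C at 7.49%. In 5' UTRs A reached 73.3% of 7880 sites, against 37.4% of 9098 in coding sequence and 39.8% of 2737 in 3' UTRs. T went the other way, from 19.6% in 5' UTRs to 41.1% in coding sequence and 50.2% in 3' UTRs. The base composition of each part was not used, so these shares are not relative to the bases available. The odds of A against other bases were 4.14 times higher in 5' UTRs than in 3' UTRs (Fisher's exact test, two-sided, p = 1.52e-211, adjusted p = 3.81e-211 over 10 tests). That p-value treats sites of the same gene as independent and does not measure the spread between genes. The share of A was 43.5% among sites found in 2 IPs, 52.7% in 3 and 64.7% in 4. The authors' peak height at truncation sites had a median of 15.7 at A and 13.5 at other bases. How it was combined over IPs is not given in the sources used here. The difference had a two-sided permutation p = 1e-05, the smallest that 100000 resamples can give. The resampling ignored gene and transcript part, so this p-value too treats sites of the same gene as independent. By part, a higher median at A than at T was seen in 5' UTRs (20.2 against 15.3), but in coding sequence the medians were 12.6 at A, 12.5 at T and 14 at C, and in 3' UTRs 14.2 at A and 14.7 at T.

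The third question was whether mutations and truncations marked the same positions. A truncation site lay within 3 nt of 47.0% of exonic C-to-T sites (45.7% to 48.2%), against 4.57% expected at other positions of the same transcript part of the same gene. This was 10.3 times the expectation (gene bootstrap interval 9.11 to 11.6, one-sided permutation p = 0.0001, the smallest that 10000 draws can give). Most of it sat at the nucleotide directly upstream of the converted C, where 2208 truncation sites were found and 2182 of them (98.8%) were at A. Among truncation sites at A, 18.3% had a C-to-T site directly downstream (17.7% to 19.0%), against 0.269% of those at T (0.174% to 0.415%), an odds ratio of 83.3. Examples were SCAP (C-to-T at chromosome 2R, 6035788, minus strand, 5' UTR in exon 1 of 7, 14.7% conversion, truncation at 6035789) and the metalloprotease gene kuz (chromosome 2L, 13551486, plus strand, 5' UTR in exon 2 of 13, 5.93% conversion, truncation at 13551485).

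**Figure D1:**
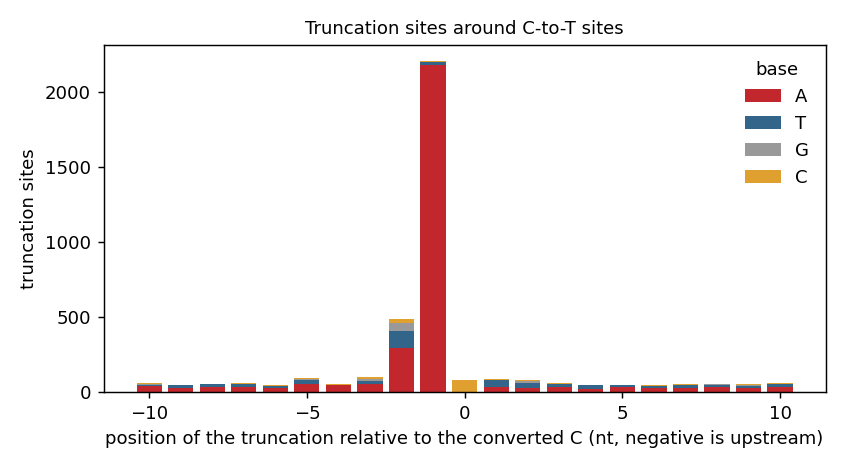
Truncation sites by their distance in nucleotides from C-to-T sites, coloured by base at the truncation; negative distances are upstream. The bar at -1 holds 2208 truncation sites, 2182 of them at A, and the next highest bar, at -2, holds 489.

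By number of converted tags, the highest exonic C-to-T sites were in CG5174 (3' UTR, 89.1 tags of 618.6, 14.1%), CG5346 (5' UTR, 78.3 tags, 9.40%), SCAP (76.9 tags), RpS28b (3' UTR, 75.6 tags, 16.8%) and Fim (5' UTR, 74.1 tags, 6.80%). Each was found in 4 IPs and had a truncation directly upstream. The tallest exonic truncations were in Rip11 (5' UTR, height 489.7), RpS15 (coding sequence, 475.3), eEF2 (coding sequence, 420.7 and 389.9) and Fim (5' UTR, 413.7), and all 5 were at A.

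The fourth question was where along mRNAs the sites lay. 5' UTRs were over-represented in both lists. They held 62.3% of C-to-T sites (61.0% to 63.5%) where their length predicted 19.2%, a ratio of 3.24 (gene bootstrap interval 3.04 to 3.44). They held 40% of truncation sites where 17.1% was predicted, a ratio of 2.34 (2.25 to 2.43). Coding sequence was under-represented, at 0.516 times the expectation for C-to-T sites and 0.795 times for truncations, and so were 3' UTRs, at 0.376 and 0.559 times. Each of these 6 ratios had a two-sided permutation p = 0.0002, the smallest that the draws can give, and an adjusted p = 0.000209 over 24 tests.

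Bases differed in this respect. Truncations at A were 3.07 times over-represented in 5' UTRs (2.96 to 3.18), with 56.2% of sites there. Those at T were so by 1.45 times (1.36 to 1.55), with 23.2% of sites. The expectation counted positions of every base, and base composition was not used. Neither these ratios nor the gap between them is therefore relative to the A or T positions available. The gap in 5' UTR share was 33.0 percentage points (gene bootstrap interval 31.5 to 34.6). C-to-T sites exceeded all truncation sites by 22.3 points (17.9 to 26.3), and by 6.05 points when only truncations at A were counted, a setting chosen after the data were seen. C-to-T sites with a truncation at A directly upstream lay in 5' UTRs in 88.9% of cases, against 49.6% of those with no truncation within 3 nt.

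**Figure D2:**
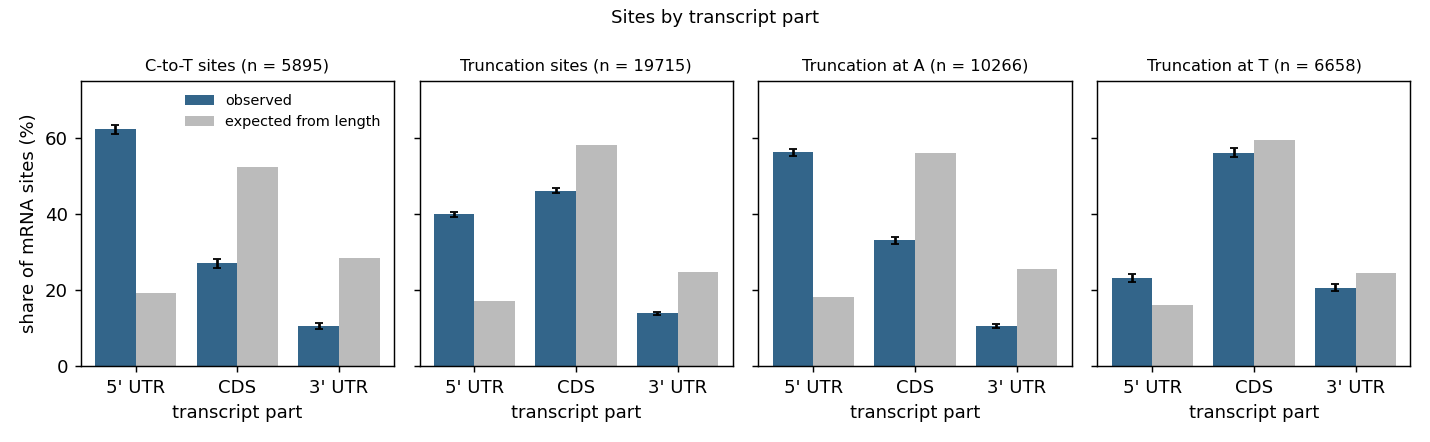
Share of exonic sites in each transcript part (percent, blue bars with 95% Wilson intervals) beside the share expected from the length of that part in the same genes (grey bars), for C-to-T sites, all truncation sites and truncations at A and at T. The 5' UTR share is 62.3%, 40%, 56.2% and 23.2% in turn.

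Paired evidence followed the same division. A truncation at A stood directly upstream of 49.1% of C-to-T sites in 5' UTRs (1803 of 3672), 19.7% in 3' UTRs (124 of 629) and 6.34% in coding sequence (101 of 1594). For the 630 coding sites outside ribosomal protein and elongation factor genes the share was 13.7%. 5' UTRs and coding sequence differed by an odds ratio of 14.3 (Fisher's exact test, two-sided, p = 1.17e-229, adjusted p = 3.89e-229). This test counts sites of the same gene as independent, so its p-value does not measure the spread between genes. Coverage differed too, with a median of 238 tags at 5' UTR sites and 464 at coding sites. In the lowest quartile of each part by tags, where median coverage was 94.2 tags in 5' UTRs and 92.3 in coding sequence, the shares were 59.5% and 13.3%.

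**Figure D3:**
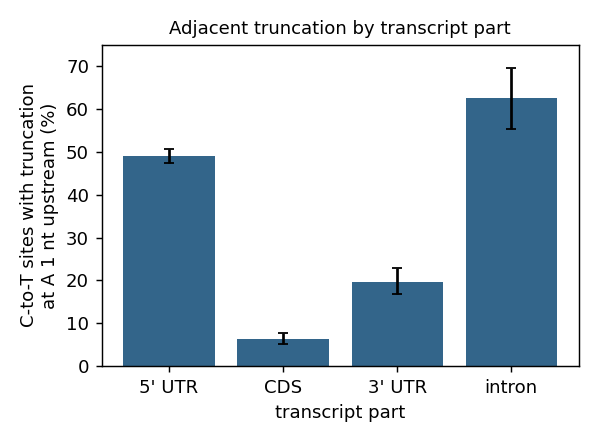
Percent of C-to-T sites in each transcript part that have a truncation at A 1 nt upstream, with 95% Wilson intervals. The share is 49.1% in 5' UTRs, 6.34% in coding sequence, 19.7% in 3' UTRs and 62.6% in introns.

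Toward the start codon, C-to-T sites thinned out within the 5' UTR, from 4.44 times the expectation in step 4 of 10 to 1.75 in step 10 and 0.728 in step 1 of the coding sequence. Within 50 nt of the start codon lay 7.23% of C-to-T sites against 5.07% expected over whole mRNAs (ratio 1.43, interval 1.26 to 1.62) and 7.44% of truncation sites against 4.78% (ratio 1.56, 1.48 to 1.64), each with a two-sided permutation p = 0.0002, the smallest possible, and adjusted p = 0.00048 over 12 tests. This expectation does not allow for the 5' UTR excess, so the ratios are no sign of an excess at the start codon itself. Around the stop codon the ratios were 0.929 for C-to-T sites (permutation p = 0.234) and 1.04 for truncation sites (permutation p = 0.220), neither past the threshold. Here too the expectation does not allow for the 5' UTR excess. Over the whole coding sequence and 3' UTR the ratios were lower, at 0.516 and 0.376 for C-to-T sites and 0.795 and 0.559 for truncation sites. Among sites in 4 IPs both stop codon ratios lay below 1, while C-to-T sites turned above 1 in 2 other settings. The 4-IP ratios were 0.793 (permutation p = 0.0396, gene bootstrap interval 0.591 to 1.01) and 0.872 (permutation p = 0.0496, interval 0.753 to 0.981). These 2 p-values were not adjusted for the number of tests, and the C-to-T interval holds 1. Truncations at T had a ratio of 1.33 around the stop codon (permutation p = 0.0002) and those at A 0.833 (permutation p = 0.0006). The latter is still above the 0.590 and 0.416 that truncations at A had over the whole coding sequence and 3' UTR. None of these expectations used base composition. Within 50 nt of the transcription start, C-to-T sites were sparser than expected over whole mRNAs (0.788, permutation p = 0.0014). Truncation sites did not pass the threshold there (1.07, permutation p = 0.0772). This expectation does not allow for the 5' UTR excess either. Over whole 5' UTRs the ratios were higher, at 3.24 for C-to-T and 2.34 for truncation sites. The ratio of 1.07 therefore does not show that truncations were as frequent there as in 5' UTRs at large. Neither call at the transcription start was stable across settings. The C-to-T ratio was 0.886 among sites in 4 IPs (permutation p = 0.360), but 0.644 above the median of converted tags and 0.363 with all 3 aligners (permutation p = 0.0002 each). With all 3 aligners, a setting chosen after the data were seen, the truncation ratio was 0.785 (permutation p = 0.0002). The 3672 C-to-T sites of 5' UTRs lay a median of 295 nt from the transcription start.

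**Figure D4:**
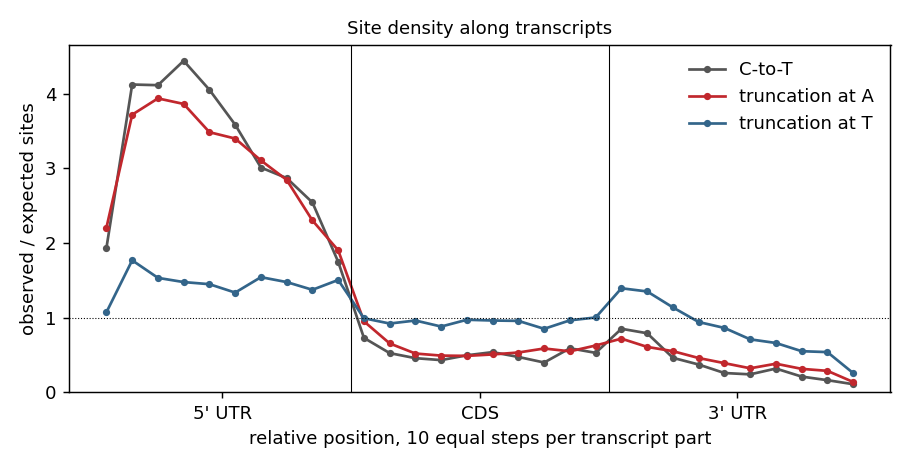
Observed over expected number of sites along the 5' UTR, coding sequence and 3' UTR, each divided into 10 equal steps, for C-to-T sites and for truncations at A and at T. Over the whole 5' UTR the ratios are 3.24, 3.07 and 1.45, and the dotted line marks a ratio of 1.

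The fifth question was which groups of genes carried sites. Of 13968 nuclear protein-coding genes, 3807 had an exonic site in either list. Among 22 gene lists, 16 had a higher share of genes with sites than other genes and 1 a lower share (Fisher's exact test, two-sided, adjusted over the lists). Against lists matched on exonic length, 12 of the 16 remained higher. Since mRNAs must be expressed to be seen, these shares mix expression with methylation.

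Ribosomal protein genes had sites in 83 of 90 cases (92.2%, adjusted p = 1.37e-37, Fisher's exact test), with RpL23A, RpL8, RpL5 and RpL3 ahead at 51 to 57 sites. Their 1108 C-to-T sites were mostly in coding sequence (799), their median conversion was 1.65% at 585 tags, and 2.71% had a truncation at A directly upstream. Translation initiation factors had sites in 32 of 44 (72.7%), led by eIF4H1 with 39. The replication-dependent histone genes had none in 111 (Fisher's exact adjusted p = 5.56e-15); their mRNAs lack poly(A) tails and the copies are near-identical, so absence here is limited evidence.

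In the list of axon growth and guidance genes, the subject of the study's title, 25 of 43 had sites (58.1%, Fisher's exact adjusted p = 5.10e-05), but against 51.1% in lists matched on exonic length this did not pass the threshold (permutation p = 0.433, adjusted p = 0.476). Of their C-to-T sites 94.2% lay in 5' UTRs, against 62.3% of all exonic C-to-T sites, a difference that was not tested. It was not particular to them: the share was 91.2% in Notch, 92.6% in Hippo, 90.4% in ecdysone response and 100% in insulin and TOR genes. The other lists with C-to-T sites had lower shares, down to 0% in oxidative phosphorylation and proteasome genes. All 25 axon genes with sites had a 5' UTR site, against 60.8% of other genes with sites (Fisher's exact adjusted p = 5.11e-05 over 22 lists). This comparison does not allow for the number of sites per gene or for 5' UTR length. The tyrosine kinase gene Abl had 33 sites, its antagonist ena 28, the guanine nucleotide exchange factor gene trio 27 and Dscam1 18, and of their C-to-T sites 11 of 12, 11 of 11, 3 of 5 and 5 of 5 lay in the 5' UTR. Ribosomal protein genes were the other list with a higher share of genes with a 5' UTR site, at 97.6% (Fisher's exact adjusted p = 4.36e-14). Yet 10.9% of their C-to-T sites lay in 5' UTRs (121 of 1108), so this call does not mean that their sites favoured 5' UTRs. Among sites in 4 IPs the axon list kept its call (Fisher's exact adjusted p = 0.00467) and the ribosomal protein list did not (0.394). Among paired sites the axon list kept its share of 100% but lost its call (Fisher's exact adjusted p = 1), and the ribosomal protein list turned, at 20%. Notch pathway genes had sites in 13 of 17 cases, among them kuz (31), gro (22), H (14) and mam (13). Hippo pathway genes had them in 11 of 14, among them kibra (21), wts (20) and sd (12). Insulin and TOR genes had them in 11 of 14, led by S6k and Pdk1 with 13 each, and all 14 of their C-to-T sites were in 5' UTRs. Of the 15 ecdysone response genes 10 had sites, led by ImpL2 with 35, but the share of 66.7%, against 47.4% in length-matched lists, did not pass the threshold there (permutation p = 0.197, adjusted p = 0.241). All 15 C-to-T sites of the receptor gene EcR and all 6 of Eip75B lay in 5' UTRs.

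The genes of the m6A pathway, a list that includes Fmr1, and a list of cytoskeleton genes were followed one by one. Of 11 m6A pathway genes 7 had sites (Fisher's exact adjusted p = 0.0172; against length-matched lists the permutation adjusted p was 0.205). The nuclear reader gene Ythdc1 (chromosome 3L, 3370451 to 3374170, minus strand) had 33 sites, and 13 of its 17 C-to-T sites and 12 of its 16 truncations were in the 3' UTR. Its strongest C-to-T site with a truncation at A directly upstream was at 3371160 in exon 3 of 3, with 20.7 of 638.8 tags converted (3.26%). The writer complex gene fl(2)d had 16 exonic sites, its strongest C-to-T site among them at chromosome 2R, 13824081, in the coding sequence of exon 1 of 4 (2.08% of 1118 tags). Its introns held 7 C-to-T and 17 truncation sites besides, which these counts leave out. nito had 8 sites, all in the 3' UTR. The cytoplasmic reader gene Ythdf had 7, including a 5' UTR C-to-T site at chromosome 3R, 25039001 (5.99% of 182.6 tags) with its truncation at 25039002. Hakai had 2 and Flacc 1. Fmr1, the fly gene of the fragile X protein, had 15 sites, 13 of them truncations, and its strongest C-to-T site was in the 3' UTR at chromosome 3R, 10101756 (3.38% of 176.8 tags, found in 2 IPs). The catalytic subunit genes Mettl3 and Mettl14 and the genes vir and Sxl had none.

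In the list of cytoskeleton genes, which does not include Fmr1, 28 of 30 had sites (93.3%, Fisher's exact adjusted p = 2.52e-13), with the ERM protein gene Moe at 41, msn and Act42A at 31 and ena at 28. Rho1, Act5C and Arp3 had 23 each, alphaTub84B 24, flw and chic 22, betaTub56D 19, sqh 18, tsr 17, Cdc42 15, Rac2 14, cpb and zip 13, dia 11, and spir and Arp2 10. Single figures were found for cpa (9), Cyfip (7), Rac1, capu and mbc (5 each) and SCAR, futsch and ssh (1 each). Abi and Hem had none. Of their C-to-T sites, Moe had 9 of 13 in the 5' UTR, msn 3 of 11, Act42A 0 of 10 and ena 11 of 11.

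All 12 glycolysis genes had sites, led by Eno (22) and PyK (19), and SR and hnRNP splicing factors had them in 22 of 23, led by sqd (32) and heph (15). Oxidative phosphorylation genes had sites in 46 of 80 (57.5%) and proteasome genes in 28 of 40 (70.0%), led by ATPsyngamma (17) and Rpt6 (14). Their 8 and 4 C-to-T sites stood against 183 and 88 truncations, and 116 and 66 of these lay in coding sequence. In the C-to-T list alone the shares fell to 6.25% and 7.50%, not past the threshold (Fisher's exact adjusted p = 0.607 and 1). Chaperones had sites in 9 of 13, led by Hsc70-4 (54) and Hsc70-3 (50), and Polycomb and trithorax genes in 13 of 18, led by mor (13) and osa (11). Of 6 dosage compensation genes, msl-1 and msl-2 had sites.

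Markers of other cell types were nearly free of sites. Haemocyte markers had sites in 6 of 10 (Fisher's exact adjusted p = 0.0388; against length-matched lists the permutation adjusted p was 0.575), led by SPARC with 45 and crq with 12. Of 7 germline markers AGO3 had 2 sites, and 0 of 10 neuron, 0 of 8 muscle and 0 of 8 fat body and gut markers had any. None of these 4 lists passed the threshold (Fisher's exact adjusted p = 0.682, 0.0873, 0.129 and 0.129 in turn); against length-matched lists the neuron markers alone did (permutation adjusted p = 0.00391).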

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

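Of the tests in this part, those on single aligners and on ribosomal protein and elongation factor genes were set before their results were seen; the others were chosen after. No biological explanation was tested, since all site values come from 1 group.

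Sites outside nuclear genes lay beyond the main measurement. The mitochondrial genome held 42 C-to-T and 170 truncation sites, led by mt:CoI with 15 and 26. None of the 42 had a truncation at A directly upstream, which allows a share of up to 7.14% (3 counts of 42). Their median coverage was 519.9 tags, and coding C-to-T sites of like depth (median 591.6 tags) had such a truncation in 2.01% of cases, so no difference was detectable. T was the base at 55.9% of the mitochondrial truncations (48.4% to 63.1%). Repeats, by the authors' labels, held 30 C-to-T sites, 8 of them with such a truncation (26.7%), and 309 truncation sites, led by the internal part of the Copia retrotransposon with 69.

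Few coding C-to-T sites had a truncation at A directly upstream (6.34%). Sites from single aligners are argued against as the whole account, since 7.63% of coding sites found with all 3 aligners had one (interval 5.84% to 9.92%). Ribosomal protein and elongation factor genes alone are argued against too, since without them the share was 13.7% (11.2% to 16.6%), far from the 49.1% of 5' UTRs. Low-rate errors in deeply covered mRNAs may account for part: the share was 4.42 times higher in the lowest quartile of coding sites by tags than in the highest (2.07 to 12.8). Between the same quartiles it also fell from 59.5% to 31.3% in 5' UTRs and from 32.3% to 2.55% in 3' UTRs. This trend with tags was thus not particular to coding sequence, and by itself it cannot say why coding sites in particular had few. Low-rate errors are not the whole account. In the lowest quartiles by tags (medians 94.2 and 92.3) the share was still 59.5% in 5' UTRs and 13.3% in coding sequence. The ratio of 4.42 may itself come in part from the higher conversion that sites with few tags need to be listed.

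Truncations at T made up 32.5% of the truncation list. Of these, 5.47% had a C-to-T site or a truncation at A within 3 nt (4.98% to 6.01%), so most did not lie beside a listed site of that kind. This cannot decide whether they lay beside a modified base, since such a base may not have been listed. Thin support may account for part, since the share of T fell from 39.3% in 2 IPs to 31.8% in 3 and 22.2% in 4 (21.2% to 23.2%). It is argued against as the whole account, since T did not vanish in 4 IPs. The bound used for this was chosen after the results were seen. Crosslinking at uridines irrespective of m6A stays open, as untested, because no control library was used.

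The over-representation of 5' UTRs in the truncation list is argued not to come from reverse transcription ending at mRNA 5' ends, since without positions within 50 nt of a transcription start the ratio was 2.68 (2.56 to 2.79). The order of transcript parts is argued against too, with a ratio of 2.41 (2.32 to 2.51) when 3' UTR and coding sequence took precedence. Deeper coverage of 5' UTRs cannot be told apart from it here. The 5' UTR ratio of truncations at A was 2.12 times that of truncations at T (2.01 to 2.23). Deeper coverage would raise both bases alike, so it would give this quotient only if base composition also differs between parts. Neither coverage nor composition was used. By the first bound of 2, which the interval clears, coverage would have been argued against; the bound was raised to 3 after the value was seen, and it is this change that leaves the outcome open.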

How the results depend on the processing

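The 5' UTR excess and the shortage in coding sequence and 3' UTRs kept direction and call in every alternative run, the 5' UTR ratio ranging from 3.11 to 3.89 for C-to-T sites and 2.31 to 3.07 for truncations. The start codon ratios did so too, though they do not allow for the 5' UTR excess. The excess of shared sites kept its call, but its ratio of 10.3 ranged widely: 19.1 in 4 IPs, 18.7 within 1 nt, 4.16 within 10 nt and 1.98 at the same position. The gap in 5' UTR share between the lists kept its sign but shrank from 22.3 points to 9.15 in the top quartile and 6.05 against truncations at A only. Of the main results, 102 alternative values held, 16 moved, 6 reversed, 1 grew stronger and 1 weaker. Of the others 95 held, 34 moved, 5 reversed and 8 grew weaker, the moved values being site counts of named genes under filters. Settings on aligners, authors' labels, truncations at A and paired sites were chosen after seeing the data. Fewer sites follow from a filter by construction; for every other change the cause was not tested.

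Sites in 4 IPs left 2151 C-to-T sites in 703 genes and 6290 truncation sites in 2092 genes; all 3 aligners left 2677 in 786 genes and 12872 sites. The share of A among truncations rose to 56.9% above the median height, 62.6% in the top quartile, 64.7% in 4 IPs and 61.7% with all 3 aligners. Around the stop codon, the C-to-T ratio turned to 1.05 above the median of converted tags and 1.05 with all 3 aligners, and was 0.793 in 4 IPs. The truncation ratio turned to 0.872 in 4 IPs and 0.975 with all 3 aligners. Both 4-IP ratios passed the threshold only without adjustment for the number of tests (permutation p = 0.0396 and 0.0496), and the C-to-T gene bootstrap interval holds 1. At the transcription start, the C-to-T ratio of 0.788 lost its call at 0.886 in 4 IPs but fell to 0.363 with all 3 aligners. The truncation ratio there turned to 0.946 in 4 IPs and 0.785 with all 3 aligners. The latter passed the threshold (permutation p = 0.0002, the smallest possible). None of these stop codon and transcription start ratios allows for the 5' UTR excess.

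Gene lists with a higher share of genes with sites fell from 16 to 12 against length-matched lists, 14 in the C-to-T list alone and 12 with paired sites. Lists with a lower share rose from 1 to 2 against length-matched lists. The count for paired sites sets members against all protein-coding genes, so it mixes in expression. Among genes with sites, only ecdysone response genes had a higher share with a pair (70.0% against 24.3%, Fisher's exact adjusted p = 0.0328). Oxidative phosphorylation and proteasome genes had lower shares there (2.17% and 3.57%, Fisher's exact adjusted p = 0.00174 and 0.0496). The C-to-T list alone turned oxidative phosphorylation (6.25%) and proteasome genes (7.50%), as did paired sites (1.25% and 2.50%). Among lists with 5' UTR sites, higher lists numbered 1 in 4 IPs and 0 with paired sites in place of 2, and lower ones 1 and 2 in place of 0; for paired sites the axon call was lost at an unchanged share of 100% and the ribosomal protein share turned to 20%. The higher peak at A over other bases held in all 3 alternatives, each of which pools transcript parts; by part, A was not above T in 3' UTRs (14.2 against 14.7).

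All motif alternatives (DRACH, RRACH, base-matched controls, 5' UTR share by motif) were not run, since the genome sequence was not used here, nor was leaving out each replicate. No paired analysis was possible because the values are combined over replicates. Coverage at unlisted positions limits any reading of site absence.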

Other observations

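Intronic C-to-T sites often had a truncation at A directly upstream: 109 of 174 (62.6%, 55.3% to 69.5%), with a median of 123.4 tags. In 5' UTRs the share was 59.5% (56.3% to 62.6%) in the lowest quartile of sites by tags (median 94.2); the 2 shares were not tested against each other. SNF4Agamma had 11 intronic C-to-T sites, 7 of them with such a truncation, Pvf2 had 9 (4), mask 9 (5), fl(2)d 7 (4) and tai 7 (3). These genes were chosen after their values were seen. The intronic C-to-T sites of fl(2)d lay between 13822488 and 13823720 on chromosome 2R.

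Ythdc1 had 8 C-to-T sites with a truncation at A directly upstream, 1 of them in the 5' UTR. It held 13 of the 17 C-to-T sites that the m6A pathway genes had in 3' UTRs. EcR had 6 such pairs and Eip75B 4, all in 5' UTRs.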
